A study of Mus musculus with 64 samples.

How the data were processed

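RNA was sequenced from liver, white adipose tissue (WAT), heart and muscle of male C57BL/6J mice, wild-type (CTRL) or mutant for Pklr (labelled KO), on chow or on a high-sucrose diet (HSD) for 8 weeks from 8 weeks of age, per the labels. The 64 libraries form 16 groups of 4, taken from the genotype, diet and tissue in the labels, and each tissue has 16 libraries. The labels describe 4 mice in each diet and genotype group, so the libraries of a group are taken as separate animals. The titles number the libraries of each tissue from 1 to 16; the labels do not say that a number marks a mouse.

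The authors deposited estimated counts per gene, and TPM per gene, in tables of 19521 genes. Per the submitters' processing notes, kallisto was used with the mouse genome build GRCm38; the kallisto version and the annotation release are not given in the sources used here. The deposited TPM values sum to between 816010 and 926964 per library, so the tables leave out part of the quantified transcripts. Total estimated counts were 5724366 to 12188623 per library. The counts are those of the deposited genes only.

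Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Each tissue was fitted by itself with a mean for each of its 4 groups, filterByExpr with a minimum count of 10, TMM factors, robust dispersions and the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg over the genes tested in that comparison, with a threshold of 0.05, and all are 2-sided. Each tissue had 5 comparisons: labelled KO against CTRL on chow and on HSD, HSD against chow in CTRL and in labelled KO, and the interaction of genotype and diet. A further test over 32 libraries compared the genotype effect, averaged over the diets, between liver and each other tissue. Errors after log2 fold changes are approximate standard errors with n = 4 libraries per group. Each is the size of the fold change divided by the square root of its F value, whose spread comes from all libraries fitted. For genes with almost no counts in a group, the error depends on the prior count as the fold change does. TPM values are given as mean ± SD with n = 4 unless single libraries are named.

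There were 39 gene lists fixed before the data were examined (metabolic pathways, stress responses, the circadian clock, immune and cell type markers, and neighbours of Pklr), none chosen by the study on these samples. Lists with at least 5 measured members were tested with limma 3.58.1 (camera) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists within a comparison. Named genes followed a rule fixed before the data were examined: Pklr and Pkm; for each comparison the 5 largest rises and 5 largest falls past the threshold with a mean log2 CPM of at least 1 and groups that did not overlap, without predicted or clone-named genes, Mup and Serpina1 copies (interaction tests: without the overlap criterion); and up to 4 members of a described list with the smallest p, given as values only where they did not pass. Other genes named are said to be chosen after their values were seen. Some genes that the rule selects are not reported here. Serpina1e, a copy of a multigene family, is left out for that reason.

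Tests were checked on simulated data with 200 changed genes per comparison, each gene drawn independently from the fitted means and dispersions. The simulated libraries share no variation across genes, such as a clock or length trend. The shares and false calls below may therefore not hold for the real libraries. In liver, for labelled KO against CTRL on chow, 22.4% of 1.5-fold changes, 64.2% of 2-fold changes and 84.8% of 4-fold changes were recovered over 11259 genes, with 7 false calls. In WAT for the same comparison the shares were 31.3%, 64.2% and 92.4% over 13255 genes, with 9 false calls. The 96 replicate pairs were compared for duplicate deposits: no column was identical to another, and the lowest chi-square per degree of freedom was 4.421.

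Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors in edgeR, no low-count filter, the DESeq2 Wald test, limma on log2(TPM + 1), only the 8 libraries of the groups compared, each library left out in turn, and the title number as a replicate block in the tests between tissues. Alternatives added after seeing the data were a clock score as covariate, each library's trend on log2 transcript length removed by loess, doubted libraries left out, and libraries with a length slope beyond 0.1 in either direction left out; the gene lists were also tested with the length trend removed and without such libraries in the comparisons that hold such a library. The clock score is the mean log2 CPM of Per2, Per3, Dbp, Ciart, Tef and Hlf minus that of Arntl, Npas2 and Clock. Transcript lengths came from an annotation of GRCm38 and were found for 99.12% of genes. The length of a gene was the median over its annotated protein-coding transcripts, short forms included. Removing the trend on this median may therefore leave part of a length trend. The length slope is the regression of a library's deviations from the gene means on log2 transcript length. Doubted libraries were liver CTRL chow replicates 1 and 3, WAT labelled-KO chow replicate 3, heart labelled-KO HSD replicate 4 and muscle CTRL chow replicate 3. The counts hold whole genes, so they cannot show which exons of Pklr the transcripts contain.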

Results

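The data cover gene expression in 4 tissues of wild-type (CTRL) and labelled-KO mice, the latter labelled as mutant for Pklr, the pyruvate kinase gene of liver and red blood cells. The title of the series concerns PKLR as a drug target in fatty liver disease, so the comparisons ask how the genotype and the high-sucrose diet (HSD) changed each tissue. There were 4 libraries in each of 16 groups. Total estimated counts per library were 6714622 to 12061137 in liver, 5724366 to 11927089 in white adipose tissue (WAT), 8078117 to 12188623 in heart and 6669448 to 11685928 in muscle. The liver libraries of the labelled-KO groups, at 6714622 to 7940378, all lay below those of CTRL, at 8211776 to 12061137. Mitochondrial transcripts took 36.35 to 48.55% of counts in heart, 25.24 to 31% in muscle, 6.23 to 10.6% in liver and 6.433 to 11.07% in WAT.

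Pklr (GRCm38 chromosome 3, 89136122 to 89146815) was measured at higher levels in labelled-KO than in CTRL liver, the opposite of what a loss of the transcript would give. On chow it was 211.7 ± 55.2 TPM in labelled KO and 113 ± 37 TPM in CTRL; on HSD it was 405.1 ± 63.4 and 212.6 ± 44.8 TPM. In both diets every labelled-KO library lay above every CTRL library. The exact permutation test on log2 TPM gave a two-sided p of 0.0286 in each diet, the smallest that 70 arrangements of 4 against 4 can give. In the edgeR test across all genes the log2 fold change was 1.07 ± 0.26 on chow, with an adjusted p of 0.196, and 0.99 ± 0.26 on HSD, with an adjusted p of 0.22, so neither passed the threshold. Pklr was near 0 in the other tissues, with a highest library of 5.035 TPM in WAT. Pkm (chromosome 9, 59656576 to 59679372), the pyruvate kinase of most other tissues, was 4.744 to 7.058 TPM in the liver group means, 222.6 to 325.8 TPM in those of WAT, 293.8 to 350.6 TPM in heart and 530.7 to 580.8 TPM in muscle. Pklr levels alone do not show whether the labels are right, so all directions below follow the labels as deposited.

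**Figure D1:**
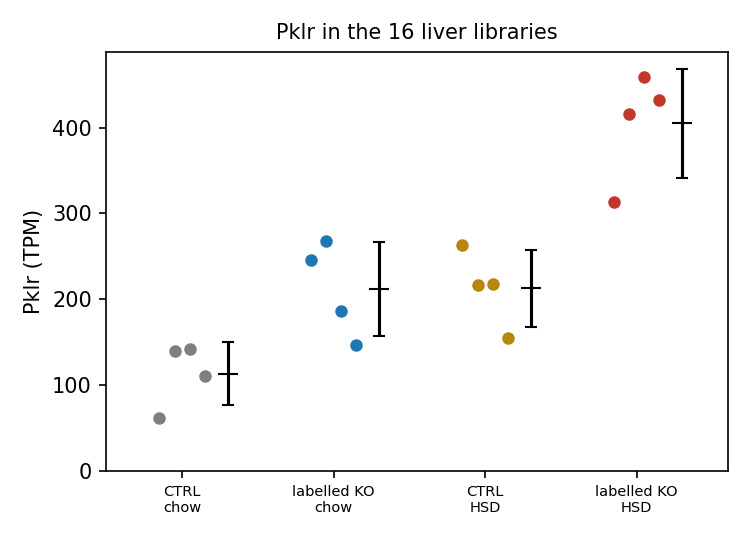
Pklr in TPM (vertical axis, starting at 0) in each of the 16 liver libraries by group; points are libraries, the bars beside them the mean and SD with n = 4. The labelled-KO libraries sit between 146.8 and 267.6 TPM on chow and 313.7 and 458.7 TPM on HSD, above the CTRL libraries of the same diet.

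In CTRL liver, genes that make fatty acids were higher on HSD than on chow. Of the 20 measured genes of de novo lipogenesis, 14 rose, and 14 passed when adjusted over the list alone. Here and below, the largest rises and falls are those among called genes with a mean log2 CPM of at least 1 and groups that did not overlap, so a list can hold larger ones. The largest rises so defined included 2 of them: Pnpla3, a lipid droplet lipase, by 4.25 ± 0.68 on the log2 scale (adjusted p = 0.00511) and G6pdx, which supplies NADPH, by 3.72 ± 0.56 (adjusted p = 0.00495). The fatty acid elongase Elovl5 rose by 1.94 ± 0.22 and the desaturase Fads1 by 1.03 ± 0.18. Pnpla3 was 9.666 ± 3.67 TPM on HSD and 0.4552 ± 0.467 TPM on chow. Pnpla5 (3.53 ± 0.93), Apoa4, an apolipoprotein (3.02 ± 0.54), and Hamp2, a hepcidin gene (2.88 ± 0.53), were the others under that filter. The list test for lipogenesis gave an adjusted p of 3.07e-19, and an adjusted p = 0.18 with an estimated correlation. Of 25 genes of pyruvate oxidation and the TCA cycle 5 rose, among them citrate synthase Cs (0.81 ± 0.15), Dlat (1.16 ± 0.21), Pdha1 (0.62 ± 0.12) and Pdk1 (0.95 ± 0.24), and 8 passed adjusted over the list alone. This list's adjusted p was 0.00123, and adjusted p = 0.58 with an estimated correlation. Of 17 glycolysis genes Gpi1 (0.77 ± 0.15) and Pfkfb1 (0.61 ± 0.15) rose, 5 adjusted over the list alone; the list's adjusted p was 0.00454, and adjusted p = 0.213 with an estimated correlation. Among 23 genes of fatty acid oxidation and ketogenesis Pdk4 (1.53 ± 0.34) and the hormone Fgf21 (1.90 ± 0.46) rose, 4 passed adjusted over the list alone, and the list did not pass (adjusted p = 0.32).

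Of the 16 acute phase genes in that comparison all had lower means on HSD, 3 passed and 12 passed adjusted over the list alone. Saa4 fell by 2.19 ± 0.44, Saa3 by 4.66 ± 1.12 and Orm3 by 4.28 ± 1.10 on the log2 scale. The list's adjusted p was 0.000208, and adjusted p = 0.798 with an estimated correlation. The chow libraries differed widely: Saa1, a serum amyloid, was 45060, 66.19, 4974 and 675.5 TPM in CTRL chow replicates 1 to 4. On HSD the highest library had 1534 TPM and the next 68.06 TPM, so CTRL chow replicate 2 was at the level of HSD. Without CTRL chow replicate 1 the log2 fold changes were -1.42 (Saa4), -1.69 (Saa3) and -1.99 (Orm3, no longer past the threshold). None of these 3 calls held through every leave-out: Saa4 was lost without CTRL HSD replicate 2, Saa3 without any 1 of the 4 CTRL HSD libraries, and Orm3 without CTRL chow replicate 3 or any 1 of the CTRL HSD libraries. The metallothionein Mt2 (fall of 6.14 ± 1.42) was 2104, 11.73, 379.8 and 15.66 TPM in CTRL chow replicates 1 to 4. In CTRL HSD libraries Mt2 was 6.075 to 12.96 TPM, so chow replicates 2 and 4 were near the level of HSD. It was at -4.05 without CTRL chow replicate 1, and its call was lost without any 1 of the 4 CTRL HSD libraries. Other large falls were Selenbp2 (-4.06 ± 0.75), Enho (-3.79 ± 0.59), the organic anion transporter Slc22a7 (-2.81 ± 0.43) and Dop1b (-2.51 ± 0.61). Selenbp2 and the steroid hydroxylase Cyp7b1 (-1.89 ± 0.39) are among 4 of 12 male-biased liver genes that fell, while Elovl3 (1.06 ± 0.27) rose and 7 passed adjusted over the list alone. The male-biased list's adjusted p was 0.0187, and adjusted p = 0.798 with an estimated correlation. Among 18 clock genes 3 rose and 6 fell, with Npas2 up by 3.16 ± 0.69 and Per3 at -2.00 ± 0.39, Per2 at -1.34 ± 0.28 and Bhlhe40 at -0.98 ± 0.18; 12 passed adjusted over the list alone. The clock list's adjusted p was 0.00454, and adjusted p = 0.18 with an estimated correlation. The cell cycle inhibitor Cdkn1a rose by 2.59 ± 0.47.

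In all, 279 genes rose and 247 fell of 11259 tested. Limma on log2(TPM + 1) split the calls 461 to 94, and the count was 1 with the clock score as a covariate and 112 without CTRL chow replicates 1 and 3. Leaving out a single library gave 330 (CTRL chow replicate 2), 220 (CTRL chow replicate 4), 177 (CTRL HSD replicate 2), 300 (CTRL HSD replicate 3) and 243 (CTRL HSD replicate 4). Of the 39 genes past the threshold that the naming rule selects, which include some not named here, 19 stayed past it with every library left out in turn; such tallies below count selected genes in the same way.

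In labelled-KO liver, HSD gave lipogenesis gene means in the same direction with few calls. Of the 20 lipogenesis genes 19 had a higher mean and none passed over all genes, with 13 passing adjusted over the list alone. G6pdx was at 3.18 ± 0.56 (adjusted p = 0.122), Fads2 at 1.23 ± 0.24, Fads1 at 0.86 ± 0.18 and Elovl6 at 1.58 ± 0.34. The list's adjusted p was 7.57e-19, and adjusted p = 0.313 with an estimated correlation. Over all genes 1 passed in edgeR, Gabbr2, a GABA-B receptor subunit, which rose by 0.94 ± 0.14 (adjusted p = 0.0478). There were 1128 genes at an unadjusted p under 0.05, where chance gives 563, 137 by DESeq2 and 0 by limma. Without labelled-KO HSD replicate 1 the edgeR count was 154; it was 2 without labelled-KO chow replicate 2, and 0 without any of the other 6 libraries. The interaction test, which asks whether the diet response differed between genotypes, called 0 genes in edgeR and 0 by limma, with 979 at an unadjusted p under 0.05 and 70 by DESeq2. Leaving out labelled-KO chow replicate 1, CTRL chow replicate 1 or CTRL chow replicate 4 gave 2, 5 and 3.

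**Figure D2:**
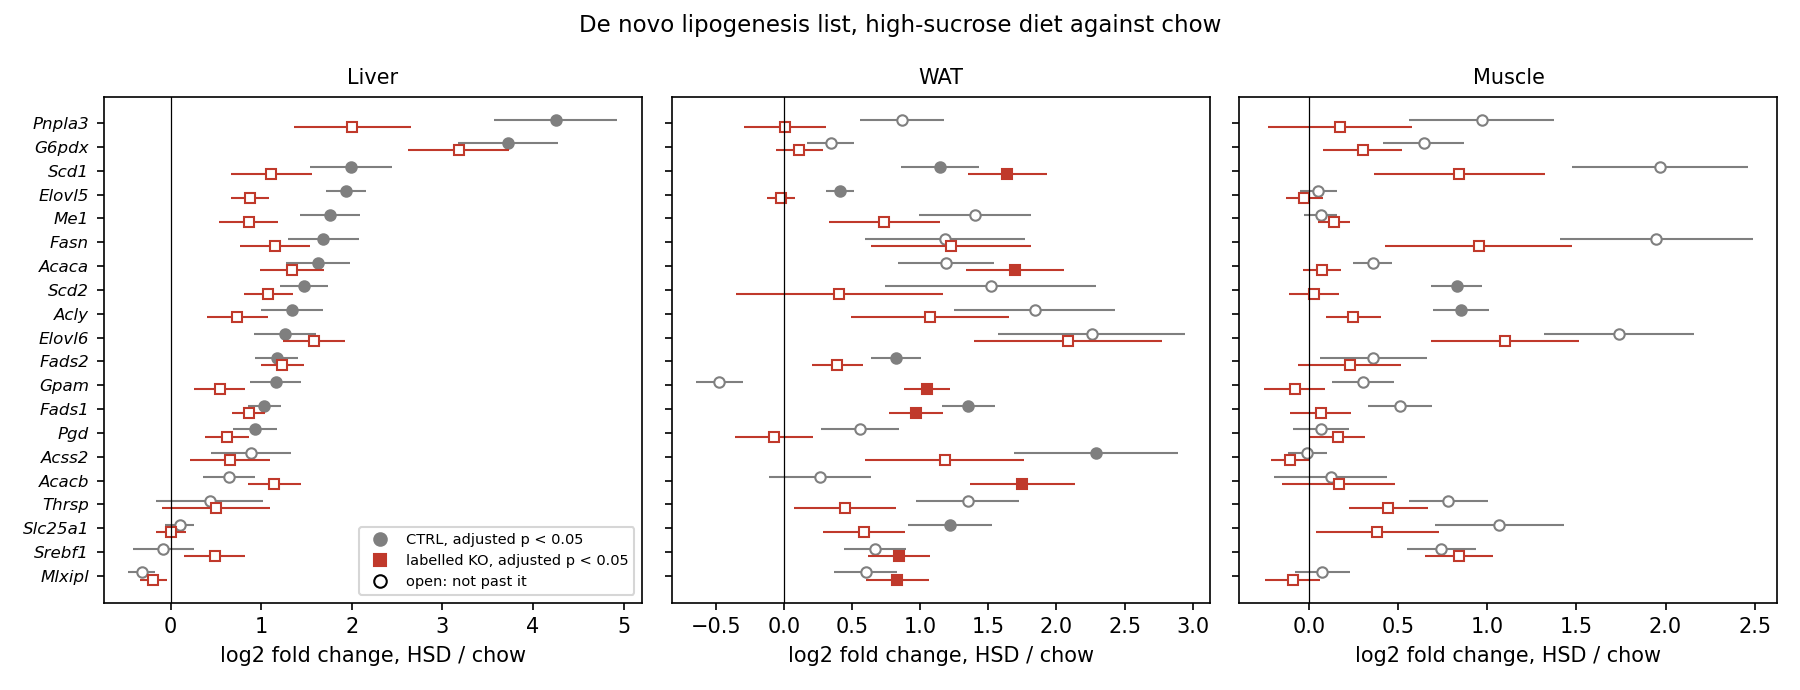
Log2 fold change of HSD against chow (horizontal axis, with SE bars) for the de novo lipogenesis genes in liver, WAT and muscle; circles are CTRL, squares labelled KO, filled where adjusted p is under 0.05. In liver 14 of 20 genes are filled for CTRL and none for labelled KO, although 19 of 20 lie above 0.

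Between labelled KO and CTRL liver on HSD, 2 genes rose and 6 fell, among them the clock genes Per3 and Arntl. Per3 rose by 2.29 ± 0.40 and the phosphate transporter Slc20a1 by 0.93 ± 0.16. Arntl, the core clock activator also called BMAL1, fell by 2.80 ± 0.45, from 6.718 ± 2.5 to 0.946 ± 0.408 TPM. Cdkn1a (-2.93 ± 0.49), the ubiquitin ligase Rnf144a (-1.84 ± 0.28) and St5 (-1.29 ± 0.20) also fell, with adjusted p from 0.0359 to 0.0478. Of 18 clock genes 16 passed adjusted over the list alone, 11 of them higher. The clock list's adjusted p was 8.19e-05, and adjusted p = 0.0279 with an estimated correlation. DESeq2 called 88 genes, the 8 libraries compared alone gave 22, and the clock score as a covariate left 0. Leaving out labelled-KO HSD replicates 1, 2 or 3, or CTRL HSD replicates 1 or 3, gave 0 each, and labelled-KO HSD replicate 4 or CTRL HSD replicate 2 gave 2 each; none of the 7 selected genes stayed past the threshold through every leave-out.

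On chow the genotype comparison in liver called 0 genes in edgeR and 0 by limma, with 1377 genes at an unadjusted p under 0.05 (chance gives 563) and 153 by DESeq2. All 16 acute phase genes had lower means in labelled KO and 14 passed adjusted over the list alone, with Saa1 at -7.50 ± 1.94 (adjusted p = 0.196) and Lcn2 at -8.12 ± 2.16; the wide CTRL chow Saa1 levels given above enter this comparison. Of 19 genes of the unfolded protein and amino acid stress response 15 had higher means and 5 passed adjusted over the list alone, with the chaperone Hspa5 at 0.93 ± 0.15 (adjusted p = 0.12), Manf at 1.03 ± 0.19, Creld2 at 1.06 ± 0.21 and Hyou1 at 0.82 ± 0.22. Both lists had an adjusted p of 7.08e-09; with an estimated correlation the adjusted p was 0.38 for the acute phase and 0.134 for the stress response. Without CTRL chow replicate 2 the count was 6.

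In CTRL WAT, HSD raised some mitochondrial and lipogenic genes and lowered some vessel and matrix markers. Of 81 genes of oxidative phosphorylation 34 rose, none fell, and 65 passed adjusted over the list alone, with Ndufa4 at 0.57 ± 0.10, Uqcrh at 0.53 ± 0.10, Cox6c at 0.59 ± 0.12 and Ndufa12 at 0.58 ± 0.12. The list's adjusted p was 4.55e-37, and adjusted p = 0.136 with an estimated correlation. Of 20 lipogenesis genes 6 rose and 15 passed adjusted over the list alone, 14 of them higher; Fads1 rose by 1.35 ± 0.20, Fads2 by 0.82 ± 0.18, Scd1, the stearoyl-CoA desaturase, by 1.14 ± 0.28 and Elovl5 by 0.41 ± 0.10. The list's adjusted p was 5.43e-14, and adjusted p = 0.136 with an estimated correlation. Of 25 genes of pyruvate oxidation and the TCA cycle 4 rose, Pdk1 (0.78 ± 0.15), Pdhb (0.97 ± 0.20), the pyruvate carrier Mpc1 (0.86 ± 0.20) and Sdhd (0.34 ± 0.09), with 12 adjusted over the list alone. This list's adjusted p was 1.43e-10, and adjusted p = 0.292 with an estimated correlation. Pkm rose by 0.75 ± 0.18. Under the same filter, the largest rises were H2-Q10 (3.52 ± 0.53), Acss2, an acetyl-CoA synthetase (2.29 ± 0.60), Bcas1 (1.88 ± 0.44), Parm1 (1.85 ± 0.38) and Fn3k (1.64 ± 0.27).

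The 2 groups of that comparison differ in length trend. The slope of a library's deviations on log2 transcript length was 0.0236 to 0.167 in CTRL chow (mean 0.0864) and -0.01915 on average in CTRL HSD, and the oxidative phosphorylation genes are short, with a median of 655 bases. With the length trend removed, 7 of these genes were called as rises, with 52 adjusted over the list alone and a median log2 fold change of 0.345 (main test 0.443). Without CTRL chow replicates 2 and 4, the 2 with slopes over 0.1, there were 0, 10 and 0.284. Called lipogenesis rises numbered 3 and 0 under these settings, endothelial falls 3 and 0, and collagen list falls 2 and 0; adjusted over the list alone, 13 and 10, 8 and 6, and 8 and 4 passed. Of the 81 oxidative phosphorylation genes, 80 and 79 had higher means on HSD.

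Mmp12, the macrophage elastase, had the largest fall in that tissue under the filter, by 8.04 ± 0.81 on the log2 scale (adjusted p = 0.000303), from 15.13 ± 7.83 TPM on chow to 0.0143 ± 0.0286 TPM on HSD, where the 4 libraries together held 1.194 estimated counts, so the size of the fall depends on the prior count. Spp1, osteopontin (-5.75 ± 1.35), Ect2 (-3.31 ± 0.82), Cd300ld5 (-2.89 ± 0.75) and the proton pump subunit Atp6v0d2 (-2.85 ± 0.42) followed. Ect2 was at -5.25 without CTRL HSD replicate 3 and Cd300ld5 at -5.18 without CTRL HSD replicate 1. Of 17 macrophage markers 3 fell, Itgax (-1.51 ± 0.26), Gpnmb (-1.61 ± 0.32) and Cd68 (-0.76 ± 0.19), and 4 passed adjusted over the list alone. The list itself did not pass (adjusted p = 0.0891). With the length trend removed it passed at the preset correlation (adjusted p = 0.0159), the less strict of the 2 list tests here. Cd68 was at -0.50 (adjusted p = 0.0677) without CTRL chow replicate 3. All 10 endothelial markers had lower means, 5 fell and 7 passed adjusted over the list alone, with Pecam1 at -0.63 ± 0.12, Vwf at -1.83 ± 0.37, Tek at -0.52 ± 0.11 and Cdh5 at -0.69 ± 0.15; Vwf was at -1.21 without CTRL chow replicate 4. The endothelial list's adjusted p was 5.02e-07, and adjusted p = 0.136 with an estimated correlation. Of 16 stellate cell, fibroblast and collagen genes 4 fell, Col6a1 (-1.01 ± 0.18), Pdgfrb (-0.59 ± 0.11), Sparc (-0.61 ± 0.15) and Acta2 (-0.93 ± 0.25), 9 adjusted over the list alone; the adjusted p was 9.58e-07, and adjusted p = 0.136 with an estimated correlation. Among 14 white adipocyte genes the hormone Lep (-0.94 ± 0.23) and Sfrp5 (-2.28 ± 0.41) fell and the glucose transporter Slc2a4 (0.48 ± 0.11) and Retn (0.75 ± 0.19) rose, 5 passed adjusted over the list alone, and the list did not pass (adjusted p = 0.505).

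That comparison called 245 rises and 387 falls of 13255 genes. The split was 304 to 337 with DESeq2 size factors and 128 to 1320 with limma on log2(TPM + 1), and the count was 326 with the length trend removed, 287 with the clock score as a covariate and 9 without CTRL chow replicates 2 and 4. Leaving out a single library gave 147, 1024 and 151 (CTRL chow replicates 2, 3 and 4) and 94, 185, 341 and 220 (CTRL HSD replicates 1 to 4); of 38 selected genes 11 stayed past the threshold through every leave-out.

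In labelled-KO WAT, clock genes differed between HSD and chow. Matrix genes and some cell division genes were lower on HSD, and some lipogenic genes were higher. Of 18 clock genes 10 rose and 4 fell, with 15 adjusted over the list alone. Hlf rose by 2.10 ± 0.21, Tef by 1.29 ± 0.18 and Nr1d2 by 1.10 ± 0.18, and Arntl fell by 2.09 ± 0.26, from 11.57 ± 3.68 to 2.472 ± 0.712 TPM. The clock list's adjusted p was 1.62e-07, and adjusted p = 0.0477 with an estimated correlation. Of 16 stellate cell, fibroblast and collagen genes 11 fell and 13 passed adjusted over the list alone, 1 of them higher; Col6a1 fell by 1.76 ± 0.19, Col5a1 by 1.33 ± 0.19, Sparc by 1.03 ± 0.15 and Pdgfrb by 0.65 ± 0.11. The list's adjusted p was 1.23e-14, and adjusted p = 0.0404 with an estimated correlation. Of 22 cell cycle genes 6 fell, among them Cdk1 (-2.15 ± 0.48), Cdc20 (-3.15 ± 0.73), Rrm2 (-1.65 ± 0.40) and Ccna2 (-1.96 ± 0.50), 13 adjusted over the list alone; the adjusted p was 1.62e-07, and adjusted p = 0.369 with an estimated correlation. Of 20 lipogenesis genes 7 rose and 8 passed adjusted over the list alone, with Gpam at 1.05 ± 0.17, Scd1 at 1.64 ± 0.29, Fads1 at 0.97 ± 0.20 and the rate-limiting Acaca at 1.70 ± 0.36. The lipogenesis list's adjusted p was 1.86e-08, and adjusted p = 0.35 with an estimated correlation. Of 25 TCA cycle and pyruvate oxidation genes 5 rose, 16 adjusted over the list alone, including Suclg2 (0.51 ± 0.09) and Pdk1 (0.81 ± 0.15); the adjusted p was 4.17e-09, and adjusted p = 0.369 with an estimated correlation. Of 18 fatty acid oxidation genes 4 rose, Acot2 (0.89 ± 0.17), Ehhadh (0.74 ± 0.15), Ppara (1.03 ± 0.21) and Cpt2 (0.43 ± 0.12), 8 adjusted over the list alone; the adjusted p was 0.00409, and adjusted p = 0.414 with an estimated correlation. Among 6 fructose handling genes the fructose transporter Slc2a5 (3.90 ± 1.01, and 2.03 with adjusted p = 0.136 without labelled-KO HSD replicate 4) and Sord (0.42 ± 0.08) rose, 3 adjusted over the list alone; the adjusted p was 0.00863, and adjusted p = 0.209 with an estimated correlation.

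The largest rises there under the filter, which leaves out Slc2a5, were Ciart (3.13 ± 0.61), Prom1 (3.01 ± 0.76), Clic6 (2.93 ± 0.75), Ccl28 (2.77 ± 0.80) and Dbp (2.68 ± 0.43). The largest falls under it were Uqcc1 (-6.81 ± 1.03), Mmp12 (-3.64 ± 0.61), Prss51 (-3.60 ± 0.96), Cdc20 and Prnd (-2.82 ± 0.55). Without labelled-KO HSD replicate 2 Prom1 was at 1.78 (adjusted p = 0.0901) and Ccl28 at 1.83 (adjusted p = 0.168), and without replicate 3 Prss51 was at -6.12. Uqcc1 was 5.237 ± 2.61 TPM on chow and 0.1193 ± 0.234 TPM on HSD (2.058 estimated counts over the 4 libraries, so the size of the fall depends on the prior count). Of 13255 genes 358 rose and 488 fell. The count was 0 with the clock score as a covariate, and limma on log2(TPM + 1) split it 156 to 963. Leaving out labelled-KO chow replicates 1, 2 or 4 gave 502, 360 and 526, and labelled-KO HSD replicates 3 or 4 gave 358 and 477; of 41 selected genes 26 stayed past the threshold through every leave-out. The diet calls of the 2 genotypes shared 39 rises, where independent lists would share 6.62 (one-sided Fisher's exact p = 1.8e-19), and 81 falls, where 14.2 would be shared (p = 4.55e-39); genes are not independent, so these p-values are descriptive.

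Between labelled KO and CTRL WAT on chow, falls outnumbered rises by 729 to 156. Under the filter on overlap and level, the largest falls were Tet2, a DNA demethylase (-4.34 ± 0.68), Zyg11a (-3.14 ± 0.47), the chromatin remodeller Chd2 (-2.92 ± 0.57), Elk4 (-2.77 ± 0.53) and Bdp1 (-2.77 ± 0.46). The falls had a median transcript length of 4247 bases, the rises 1345 and all tested genes 2228. Under that filter, the largest rises were the liver-secreted proteins Ttr (3.67 ± 0.91) and Pzp (3.67 ± 1.01), with Pllp (2.04 ± 0.45), Igfbp2 (1.96 ± 0.53) and Bcas1 (1.86 ± 0.44). Labelled-KO chow replicate 3 carried much of the first 2: it held 35.13 TPM of Ttr, the next library of its group 2.219 TPM, and without it the log2 fold changes were 1.39 for Ttr (adjusted p = 0.114) and 0.74 for Pzp (adjusted p = 0.378). Both calls were also lost without any 1 of the 4 CTRL chow libraries. Of 8 hepatocyte markers 3 rose, Ttr, Alb (2.45 ± 0.68) and Ahsg (3.49 ± 0.99), 5 adjusted over the list alone. Labelled-KO chow replicate 3 held 271.9 TPM of Alb against 18 to 26.64 TPM in the other labelled-KO chow libraries. Without it Alb was at 0.66 (adjusted p = 0.0482) and Ahsg at 0.51 (adjusted p = 0.534), and both calls were lost without any 1 of the 4 CTRL chow libraries. The hepatocyte list's adjusted p was 0.0337, and adjusted p = 0.964 with an estimated correlation. Of 81 oxidative phosphorylation genes 77 had higher means but only Cox8b (1.35 ± 0.28) and Cox6b1 (0.39 ± 0.11) rose, 1 adjusted over the list alone; the list's adjusted p was 4.49e-11, and adjusted p = 0.964 with an estimated correlation. These genes are short (median 655 bases), and their median log2 fold change went from 0.26 to 0.154 with the length trend removed and 0.106 without CTRL chow replicates 2 and 4. Of 18 clock genes Arntl (0.84 ± 0.24) rose and Hlf (-0.91 ± 0.21), Per3 (-1.12 ± 0.28) and Nr1d2 (-0.67 ± 0.18) fell, 8 adjusted over the list alone, and the list did not pass (adjusted p = 0.33). Among 16 stellate cell, fibroblast and collagen genes Pdgfra (-0.51 ± 0.12) and Reln (-3.23 ± 0.84) fell while 12 had higher means, and 4 passed adjusted over the list alone; the adjusted p was 0.0464, and adjusted p = 0.964 with an estimated correlation.

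The count of 885 was 461 with the length trend removed, 96 with the clock score as a covariate and 16 without CTRL chow replicates 2 and 4, whose length slopes were 0.167 and 0.105. Leaving out labelled-KO chow replicates 1, 2 or 4 gave 359, 325 and 412, and CTRL chow replicates 2 or 4 gave 363 and 439; of 20 selected genes 6 stayed past the threshold through every leave-out.

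**Figure D3:**
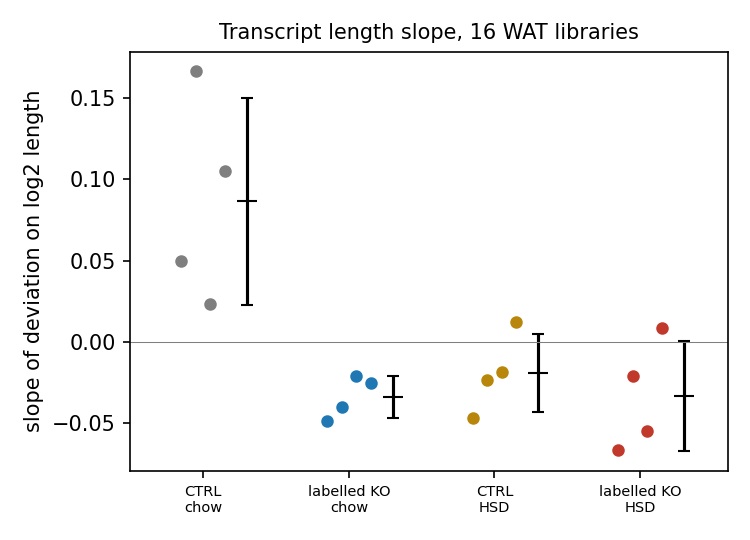
Slope of each WAT library's deviation from the gene means on log2 transcript length (vertical axis, log2 CPM per doubling of length) by group; points are libraries, the bars beside them the mean and SD with n = 4. The 4 CTRL chow libraries lie between 0.0236 and 0.167.

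On HSD the genotype comparison in WAT gave 10 rises and 4 falls, 5 of them clock genes. Hlf rose by 2.12 ± 0.21 (adjusted p = 0.000209), Dbp by 2.55 ± 0.43, Usp2 by 1.63 ± 0.25, Pard6g by 1.47 ± 0.22 and the vitamin transporter Slc5a6 by 1.37 ± 0.22. In turn Arntl (-1.64 ± 0.26), Clock (-0.81 ± 0.13), Fam180a (-0.99 ± 0.17) and Ehd3 (-0.87 ± 0.15) fell. Of 18 clock genes 3 rose and 2 fell, 16 adjusted over the list alone; the list's adjusted p was 7.23e-09, and adjusted p = 0.0303 with an estimated correlation. No gene called on chow was called in the same direction on HSD. Independent lists would share 0.118 rises and 0.22 falls, so this does not show that the genotype effect differed between the diets. In the WAT interaction, the log2 change with HSD in labelled KO minus that in CTRL was positive for 51 called genes and negative for 25; the sign gives the direction of the difference, not which response was larger. The positive ones included Hlf (3.02 ± 0.30), Dbp (2.86 ± 0.60), Spp1 (8.21 ± 1.72), Zyg11a (3.55 ± 0.64) and Fhl5 (2.83 ± 0.60). The negative ones included Uqcc1 (-7.12 ± 1.27), Cldn1 (-4.30 ± 0.80), Bcas1 (-3.63 ± 0.63), Npas2 (-2.95 ± 0.53) and C1qtnf3 (-2.70 ± 0.48). The clock score as a covariate left 0 calls in both tests. Without 1 library the HSD count was 5, 9, 1 and 60 (labelled-KO HSD replicates 1 to 4) and 4, 8, 64 and 2 (CTRL HSD replicates 1 to 4). Of 10 selected genes Hlf alone stayed past the threshold through every leave-out; Arntl was not past it without labelled-KO HSD replicates 2 or 3 or CTRL HSD replicates 1 or 4. The interaction count was 32, 23, 221 and 32 without labelled-KO chow replicates 1 to 4, 21 without labelled-KO HSD replicate 3, 20 and 48 without CTRL chow replicates 1 and 4, and 17, 25, 276 and 43 without CTRL HSD replicates 1 to 4, with 4 of 13 selected genes past the threshold throughout.

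**Figure D4:**
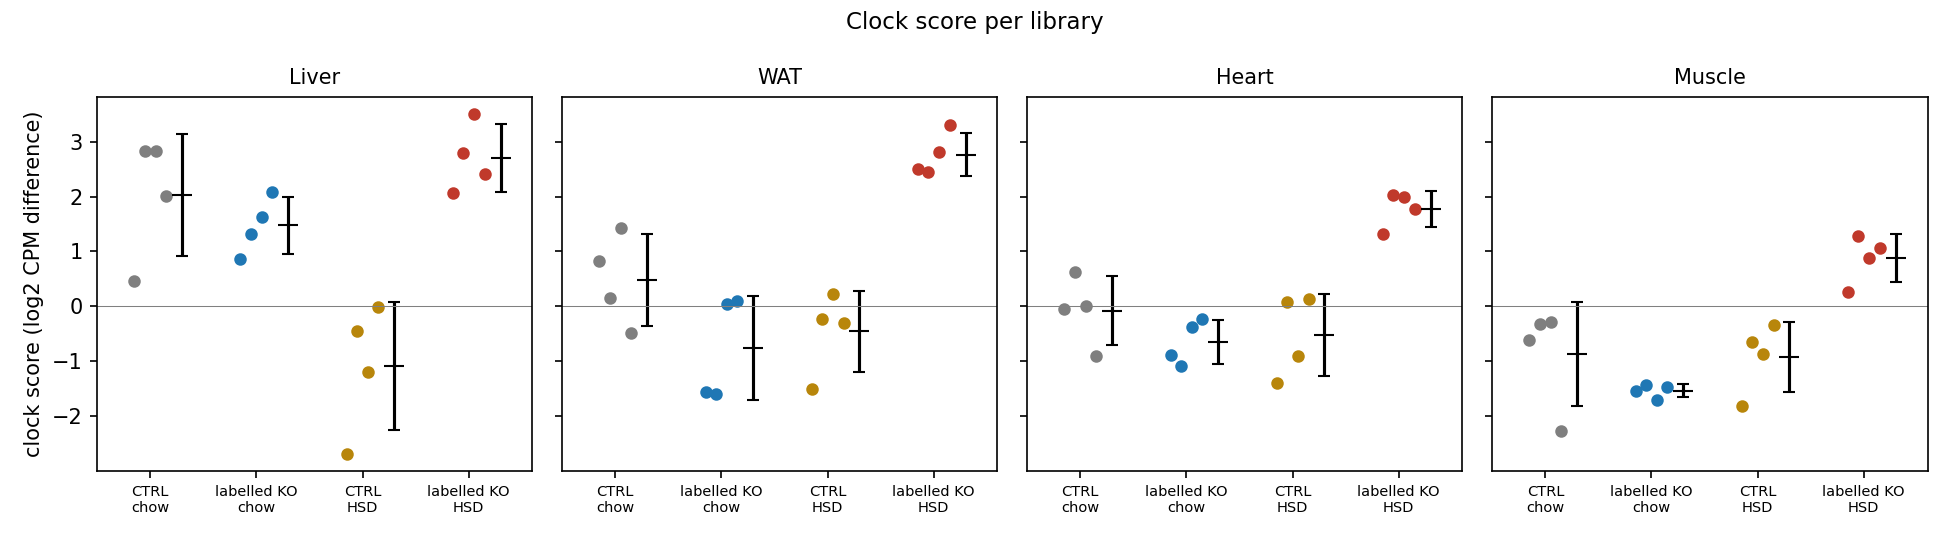
Clock score (vertical axis, mean log2 CPM of Per2, Per3, Dbp, Ciart, Tef and Hlf minus that of Arntl, Npas2 and Clock) per library in each tissue. Points are libraries, the bars beside them the mean and SD with n = 4. The labelled-KO HSD libraries are at 2.766 ± 0.39 in WAT, 1.781 ± 0.329 in heart and 0.8737 ± 0.438 in muscle, and in these 3 tissues each of them lies above every other library. In liver the CTRL HSD libraries lie below every other library instead, at -1.09 ± 1.18.

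In heart, few genes passed, and Arntl recurred. On HSD, labelled KO had lower Arntl (-1.70 ± 0.23), Cdkn1a (-1.37 ± 0.23), Tiam2 (-1.36 ± 0.22) and Adam19 (-1.07 ± 0.17) and higher Slc46a3 (0.87 ± 0.14) than CTRL. HSD lowered the antigen presentation genes H2-Ab1 (-1.32 ± 0.21) and H2-Aa (-1.005 ± 0.126), and B3galt2 (-0.88 ± 0.14), in CTRL. In labelled KO it called 3 rises and 14 falls, with the glucocorticoid target Fkbp5 (1.16 ± 0.19), Tef (0.77 ± 0.14) and Etfbkmt (0.71 ± 0.14) higher. Arntl (-1.89 ± 0.23), Tiam2 (-1.16 ± 0.22), Adam19 (-1.15 ± 0.17), Slc41a3 (-1.01 ± 0.18) and Efr3b (-0.92 ± 0.14) were lower. Of 9 endothelial markers there 1, Kdr, fell (-0.76 ± 0.11), 2 adjusted over the list alone. The 6 hepatocyte markers, led by Alb at 0.77 ± 0.16, had none past over all genes and 4 adjusted over the list alone. Each of these lists had an adjusted p = 0.0398 with an estimated correlation. Heart Alb went from 4.691 ± 0.832 TPM on chow to 7.103 ± 0.503 TPM on HSD in labelled KO. In CTRL it went from 4.102 ± 1.05 to 6.624 ± 0.734 TPM, so its rise was not particular to labelled KO. The liver group means of Alb were 31540 to 61510 TPM. Such low heart levels do not show that hepatocyte genes were active in heart. Arntl was also the 1 gene of the interaction test (-2.25 ± 0.31). In CTRL, 17 of 19 stress response genes had lower means on HSD, 10 passed adjusted over the list alone and none over all genes (list adjusted p = 7.21e-13, and adjusted p = 0.149 with an estimated correlation), with Sdf2l1 at -1.56 ± 0.37. On chow, 0 genes passed for the genotype in edgeR, DESeq2 or limma, with 447 at an unadjusted p under 0.05, below the 607 that chance gives.

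The heart counts moved when single libraries were left out. For labelled KO against CTRL on HSD (5 calls) labelled-KO HSD replicates 1, 2 or 3 or CTRL HSD replicate 3 left out gave 0, labelled-KO HSD replicate 4 gave 3, and CTRL HSD replicates 1 and 2 gave 1 and 2, and none of the 5 selected genes stayed past the threshold throughout. For HSD in CTRL (3 calls) CTRL chow replicates 2 or 4 or CTRL HSD replicates 1, 2 or 3 left out gave 1, and H2-Aa alone stayed past it throughout. For HSD in labelled KO (17 calls) the counts were 3, 1, 7 and 10 without labelled-KO chow replicates 1 to 4 and 11, 1 and 1 without labelled-KO HSD replicates 1 to 3, and Arntl alone of the 10 selected genes stayed past the threshold throughout. The interaction call was lost without labelled-KO HSD replicates 2 or 3, CTRL chow replicates 2 or 3 or CTRL HSD replicate 3, and the count was 4, 2 and 6 without CTRL chow replicate 4, CTRL HSD replicate 2 and CTRL HSD replicate 4.

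In muscle, HSD in CTRL raised 9 genes and lowered 2. Plin1, a lipid droplet coat protein (1.497 ± 0.247), Mcpt4, a mast cell protease (1.40 ± 0.25), Acss3 (1.02 ± 0.19) and Acly, ATP citrate lyase (0.85 ± 0.16), rose. Cx3cl1 (-1.09 ± 0.20) and the stress factor Ddit3 (-0.91 ± 0.13) fell. Of 20 lipogenesis genes Scd2 (0.83 ± 0.14) and Acly rose, and 12 passed adjusted over the list alone, with Elovl6 at 1.74 ± 0.42; the list's adjusted p was 1.69e-11, and adjusted p = 0.113 with an estimated correlation. Of 19 unfolded protein and amino acid stress genes 18 had lower means, Ddit3 fell and 17 passed adjusted over the list alone, with Sdf2l1 at -1.95 ± 0.39; the adjusted p was 9.61e-21, and adjusted p = 0.113 with an estimated correlation. All 82 oxidative phosphorylation genes had lower means, none passed over all genes and 25 passed adjusted over the list alone; the adjusted p was 9.37e-25, and adjusted p = 0.182 with an estimated correlation. The length slope was -0.157 in CTRL chow replicate 1, with a mean of -0.05411 in CTRL chow and 0.02196 in CTRL HSD, so short transcripts such as these (median 659 bases) read higher on chow. With the length trend removed 1 passed adjusted over the list alone and the median log2 fold change went from -0.255 to -0.175; without CTRL chow replicate 1 these were 0 and -0.165, and in both settings all 82 means stayed lower. Of 14 immediate early and heat shock genes 8 passed adjusted over the list alone and none over all genes, with Hspa1b at -1.70 ± 0.32 and Fosb at -3.93 ± 0.86; the adjusted p was 1.14e-09, and adjusted p = 0.182 with an estimated correlation. Without CTRL chow replicate 3 the count was 90, without CTRL chow replicates 1, 2 and 4 the counts were 3, 4 and 1, and without CTRL HSD replicates 1 to 4 they were 4, 0, 2 and 0; none of the 8 selected genes stayed past the threshold throughout.

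In labelled-KO muscle, HSD called Arntl alone (-1.24 ± 0.18, adjusted p = 0.0206); the call count was 0 without labelled-KO chow replicates 1, 2 or 3 or labelled-KO HSD replicates 3 or 4, 4 without labelled-KO chow replicate 4 and 2 without labelled-KO HSD replicate 2. The genotype comparisons called 0 genes on chow (1364 at an unadjusted p under 0.05, 19 by DESeq2, 0 by limma) and 0 on HSD (624, 4 and 0); chance gives 605 at an unadjusted p under 0.05, so 624 is about that number. On chow, 81 of 82 oxidative phosphorylation genes had lower means in labelled KO, none passed adjusted over the list alone, and Ndufb8 was at -0.25 ± 0.07 (list adjusted p = 1.23e-22, and adjusted p = 0.369 with an estimated correlation). The groups differ in length slope here too (-0.05411 in CTRL chow, 0.02083 in labelled-KO chow): the median log2 fold change of these genes was -0.219, -0.141 with the length trend removed (78 of 82 lower) and -0.126 without CTRL chow replicate 1 (80 of 82 lower). The interaction called 0 genes in edgeR and by limma, with 953 at an unadjusted p under 0.05 and 18 by DESeq2. Leaving out labelled-KO chow replicates 1 or 4 gave 1 call each on chow, and labelled-KO chow replicate 4 or CTRL chow replicate 4 gave 1 and 2 in the interaction.

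The genotype effect averaged over the diets differed between liver and WAT for 17 of 13893 genes. This main test took the libraries of both tissues as unrelated. With the title number as a replicate block more genes were called (given below), and 2 of the 10 selected genes were no longer past the threshold. In the main test the difference, liver minus WAT, was positive for Tet2 (2.91 ± 0.56), Ntrk2 (1.88 ± 0.34), Zfp966 (1.04 ± 0.20), Cers6 (0.98 ± 0.19) and Zzef1 (0.94 ± 0.19). It was negative for Pllp (-1.91 ± 0.33), the glycine cleavage enzyme Gldc (-1.46 ± 0.29), Sigirr (-1.11 ± 0.22), St5 (-0.89 ± 0.17) and Abca2 (-0.61 ± 0.11). The WAT side holds the chow comparison, where Tet2 and Pllp were also called and the count went from 885 to 16 without the libraries with a length slope over 0.1. The alternatives added after seeing the data were not run for this test, so a length trend in WAT may enter these differences. Without 1 title number in both tissues the count was 8, 8, 10, 10, 3, 105, 7, 1, 11 and 10 (labelled-KO chow replicates 1, 2 and 4, labelled-KO HSD replicates 1, 3 and 4, CTRL chow replicate 1, and CTRL HSD replicates 1, 2 and 4), and none of the 10 selected genes stayed past the threshold through every leave-out. Against heart and muscle edgeR called 0 genes each, with 1004 and 1189 at an unadjusted p under 0.05 (chance gives 653 and 657). Against heart the count was 1, 2 and 1 without labelled-KO chow replicate 4, labelled-KO HSD replicate 4 and CTRL chow replicate 1, and against muscle it was 1 without labelled-KO chow replicate 4. Over all comparisons 178 of 698 list tests passed at the preset correlation and 6 with an estimated one: the clock list in liver and WAT for labelled KO against CTRL on HSD and in labelled-KO WAT for HSD, the collagen list in labelled-KO WAT, and the endothelial and hepatocyte lists in labelled-KO heart.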

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

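All tests of the explanations below were chosen after the result was seen, except the test of depth for Pklr, which was written before; the counts of splits of the samples also came after. Of 132 sets of 4 libraries examined for a single library far from the others, 12 had one. A rate of about 1 in 20 would give 6.6, but that rate holds for normally distributed values. The sets include skewed TPM values, some from very few counts. They also cover genes already reported here for their values, such as Saa1 in liver and Ttr in WAT. The 6.6 is therefore not a chance expectation for these sets, and the 12 are a description only.

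Pklr was higher in labelled-KO than in CTRL liver in 32 of 32 pairs of libraries of the same diet. An exchange of the KO and CTRL labels with an allele that leaves no Pklr transcript is argued against by the lowest CTRL library, at 61.59 TPM, since one genotype would then have none. The highest liver Pkm level was 10.56 TPM, but reads moved from Pkm to Pklr would lower it too. Such sharing is argued against by muscle, with group means of 530.7 to 580.8 TPM for Pkm and 0.008942 to 0.06124 TPM for Pklr. For depth, 127 genes of similar abundance had a median log2 fold change on chow of 0.022 (SD 0.372), against 1.07 ± 0.26 for Pklr. The scaling of the libraries holds such a median near 0, so it decides little. A count taken after the result was seen argues against lower depth: 0 of the 127 had a log2 fold change on chow at or above that of Pklr. An exchange of labels with an allele that keeps part of the transcript cannot be told apart from correct labels with such an allele, because the 32 pairs look the same either way and gene totals do not show exons. A biological rise of a transcript from the mutant allele may also give this order and stays open, untested.

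Clock genes differed between the labelled genotypes on HSD: Arntl was lower in labelled KO past the threshold in liver, WAT and heart, and each of these calls was lost without some single libraries, with the direction kept. In the clock score each labelled-KO HSD library lay above every other library in WAT, heart and muscle, while in liver the CTRL HSD libraries lay below every other one, at -1.09 ± 1.18 against group means of 1.478 to 2.699. A length trend between libraries, on the median transcript length used here, is argued against as the whole cause. Arntl stayed past the threshold in 3 of 3 tissues with that trend removed. A candidate explanation is that the time of collection differed between animals: within groups, the clock scores of libraries with the same title number went together across tissues, with a mean Pearson r of 0.565 over 6 tissue pairs (0.383 to 0.786; one-sided permutation p = 0.00027; 0.541 without title numbers 9 and 13) and a mean Spearman rho of 0.517 (permutation p = 0.00017). This relies on title numbers marking animals, which the labels do not state, and it concerns differences within groups. The labels describe as many mice in a diet and genotype group as that group has libraries in each tissue. The tissues thus appear to come from the same mice. The clock differences in several tissues are then repeated views of the same animals, not independent repeats. A difference in the time of collection could also enter HSD against chow. With the clock score as a covariate, those calls went from 846 to 0 in labelled-KO WAT and from 526 to 1 in CTRL liver. The score differs between the diet groups there, so the covariate cannot separate the diet from the time of collection. An effect of genotype and diet on the clock stays open, untested.

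In WAT on chow, 729 of 885 calls for the labelled genotype were falls. Without labelled-KO replicate 3, which held liver transcripts, 713 falls were called. Liver transcripts in a labelled-KO library would give rises rather than falls, so this count was no real test of them. Without CTRL chow replicates 2 and 4, the 2 with the steepest length slope, 16 genes were called, against 82, 1177, 108, 214 and 499 without the other 5 pairs, which is what these 2 libraries would give if they were a source of the calls. With the trend on median transcript length removed, 381 calls were falls and 80 rises. So 82.6% were falls, against 82.4% before, and 75 to 92.8% with any 1 of the 8 libraries also left out. This argues against a trend on that measure as the whole source of the excess of falls. The median over annotated transcripts can misstate the length of the form expressed, so a trend that it misses is not excluded. For single genes a length trend stays open. Removing the trend left 47.7% of the falls past the threshold (348 of 729), with their median log2 fold change going from -0.577 (median SE 0.129) to -0.454 (median SE 0.12), so for the falls that were lost a length trend and a difference of genotype cannot be told apart. An effect of the genotype may contribute and stays open, untested.

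Single libraries lay far from the other 3 of their group in these measures. In liver, Saa1 was 45060 TPM in CTRL chow replicate 1 and 1534 TPM in CTRL HSD replicate 4. In WAT, labelled-KO chow replicate 3 had 35.13 TPM of Ttr and 0.8687 TPM of Pklr, CTRL chow replicate 1 had 0.8108 TPM of Pklr, and CTRL HSD replicate 4 had 0.0572 TPM of Mmp12 (1.194 counts) where the other 3 had 0. WAT Uqcc1 was 9.15 TPM in labelled-KO chow replicate 1 and 0.4701 TPM (1.963 counts) in labelled-KO HSD replicate 1. Within heart CTRL chow, Arntl was lowest in replicate 2, at 3.398 TPM. In muscle, Pklr was 0.03577 TPM (1 count) in labelled-KO chow replicate 1 and 0.07394 TPM (1.64 counts) in CTRL HSD replicate 4. The 4 values of 1 to 2 counts are at the floor and do not show that a library differs. In muscle also, the clock score of CTRL chow replicate 4 was -2.286.

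Differences between groups were tested directly. The interaction test called 76 genes in WAT and 1 in heart, where the splits do not argue against chance (below). The test of the genotype effect between liver and WAT called 17.

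The counts of calls were set against other splits of the same libraries into groups of the same sizes. For a result taken by itself, chance is argued against where the real split alone of 35 (1 of 35) gave as many calls. This is the smallest share that 35 splits can give, and 23 results were examined without adjusting for their number. Chance is therefore not excluded for these results, and small counts, such as 3 against 1 in heart, rest on little. In liver the results that the real split alone reached were labelled KO against CTRL on HSD (8, highest other split 1) and HSD in CTRL (526, highest other 0). In WAT they were labelled KO against CTRL on chow (885, highest other 106) and on HSD (14, highest other 1), and HSD in CTRL (632, highest other 8) and in labelled KO (846, highest other 1). In heart they were labelled KO against CTRL on HSD (5, highest other 1) and HSD in CTRL (3, highest other 1) and in labelled KO (17, highest other 0), and in muscle HSD in CTRL (11, highest other 0). The WAT interaction count of 76 was reached by 2 of 100 splits, and the highest other called 528, several times the real count. These splits were drawn over all 4 groups, so the differences between the real groups can enter them. What gave the 528 was not tested. The 17 genes between liver and WAT were reached by 1 of 40 splits (highest other 4).

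Where the real count was 0 every split gives as many, so the splits decide nothing there. This holds, with all 35 splits, for labelled KO against CTRL on chow in liver (highest other 39), heart (13) and muscle (8) and on HSD in muscle (1). For the counts of 1 the splits do not argue against chance. For HSD in labelled KO this count was reached by 4 of 35 splits in liver (highest other 5) and 2 of 35 in muscle (highest other 15), and the heart interaction count of 1 by 8 of 100 (highest other 4). The other counts of 0, which the splits also cannot judge, were the interaction in liver and muscle, where all 100 splits gave as many (highest other 1 and 13), and the differences between liver and heart and between liver and muscle, where all 40 did (highest other 2 each).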

How the results depend on the processing

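The clock score, the length trend, the doubted libraries, the length slope limit and the WAT overlaps under alternatives were chosen after the data were seen. Counts beyond 1.5 times the main count in either direction follow, and the cause was not tested unless stated. Comparisons are in the order labelled KO against CTRL on chow and on HSD, HSD in CTRL and in labelled KO, and interaction.

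The DESeq2 Wald test called 153, 88, 921, 137 and 70 genes in liver, 1390, 153, 1218, 1404 and 519 in WAT and 19, 4, 300, 81 and 18 in muscle; in heart it called 26, 18, 78 and 17 in the last 4 comparisons. In WAT on chow its calls were 396 higher and 994 lower. Limma on log2(TPM + 1) called 0 for HSD in labelled-KO liver and muscle, 1448 for HSD in CTRL WAT, 43 in the WAT interaction, and 0 in heart for labelled KO against CTRL on HSD, HSD in CTRL and the interaction. With only the 8 libraries compared, liver had 22 for labelled KO against CTRL on HSD and 0 for HSD in labelled KO, WAT had 569 for labelled KO against CTRL on chow and 388 for HSD in CTRL, heart had 1 for labelled KO against CTRL on HSD and 5 for HSD in CTRL, and muscle had 2 for labelled KO against CTRL on HSD, 24 for HSD in CTRL and 6 for HSD in labelled KO. Without a low-count filter, HSD in labelled KO had 2 in liver and 2 in muscle, and HSD in CTRL WAT had 420; more genes were then tested. No count moved that far with DESeq2 size factors. The TPM values used with limma were not scaled further between libraries. Its counts and splits therefore mix a change of test with a change of scaling.

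With the clock score as a covariate, labelled KO against CTRL on HSD had 0 calls in liver, WAT and heart, and HSD in CTRL had 1 in liver, 287 in WAT, 1 in heart and 27 in muscle. HSD in labelled KO had 0 in WAT, heart and muscle, the interaction had 0 in WAT and heart, and labelled KO against CTRL on chow in WAT had 96. The score differs between the groups compared, so this covariate also takes up part of the group difference. Fold changes reversed for Ciart (-0.807) and Ccna2 (0.30) for HSD in labelled-KO WAT, for Dbp (-0.18) in the WAT interaction and for Tef (-0.13) for HSD in labelled-KO heart. Ciart, Dbp and Tef are members of the score, so a weakening of their fold changes is built into this fit, though a change of sign is not.

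With the length trend removed, HSD in labelled KO had 0 in liver and 4 in muscle, HSD in CTRL had 326 in WAT and 6 in muscle, and labelled KO against CTRL in WAT on chow had 461, of which 399 were shared with the 885. Without the doubted libraries, HSD in CTRL had 112 in liver and 90 in muscle, the interaction had 2 in liver and 221 in WAT, and labelled KO against CTRL on HSD in heart had 3. Without libraries with a length slope over 0.1, liver had 0 for labelled KO against CTRL on HSD and 300 for HSD in CTRL, WAT had 16 for labelled KO against CTRL on chow, 9 for HSD in CTRL and 46 in the interaction, and muscle had 3 for HSD in CTRL.

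The WAT diet calls shared by the genotypes were 107 higher and 160 lower with DESeq2, 20 and 248 with limma, 22 and 39 with the 8 libraries alone, and 0 and 0 with the clock score. Gene list tests past the threshold went from 178 to 6 with an estimated correlation. With the title number as a replicate block, 65 genes (34 higher, 31 lower) differed between liver and WAT, and 0 between liver and heart or muscle. Labels do not state what the number marks. Within groups, deviations correlated more between libraries of the same number in 2 tissues (mean r 0.0629 to 0.106 over the 6 tissue pairs) than between others (-0.035 to -0.0209). The library of the same number was the best match within its group for 9 to 14 of 16 libraries per tissue pair. Both argue for a number marking an animal, so the fit without the block may ignore a pairing.

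Leaving out 1 library at a time gave, in the order above, 0 to 6, 0 to 9, 177 to 458, 0 to 154 and 0 to 5 in liver; 325 to 1031, 1 to 64, 94 to 1024, 358 to 992 and 17 to 276 in WAT; 0 to 0, 0 to 7, 1 to 3, 1 to 13 and 0 to 6 in heart; and 0 to 1, 0 to 0, 0 to 90, 0 to 4 and 0 to 2 in muscle. Leaving out 1 title number gave 1 to 105 between liver and WAT, 0 to 2 for heart and 0 to 1 for muscle.

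Of the values of genes that the naming rule selects, 269 of 271 kept their direction and side of the threshold with DESeq2 size factors, 239 of 271 without a filter, 208 of 261 with DESeq2, 209 of 261 with limma, 191 of 241 with the 8 libraries alone, 229 of 261 with the length trend removed, 98 of 261 with the clock score, 135 of 188 without the doubted libraries, 78 of 162 without the slope libraries, 8 of 10 with the replicate block and 1609 of 2360 with 1 library left out; the 4 reversals are those above. In simulated data 22.4 to 40.3% of 1.5-fold changes were recovered, so changes of that size can be missed at this depth and number of libraries.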

Other observations

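Of the genes near Pklr on chromosome 3, none passed in liver between labelled KO and CTRL on chow (list adjusted p = 0.0803); in WAT on chow 1 rose and 1 fell of 31, with 3 adjusted over the list alone (list adjusted p = 0.0337, and adjusted p = 0.964 with an estimated correlation). Every column of the deposited tables was assigned to a sample.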
